A study of Mus musculus with 4 samples.

How the data were processed

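Total RNA of CD8 T cell subsets sorted by flow cytometry was reverse transcribed with random primers, labelled with Cy3 and hybridised to 4 single-colour Agilent arrays, 1 per subset, per the labels' protocols. Subsets were assigned from the CD44 and CD62L phenotype in the labels. The antibodies and gates of the sort beyond these markers are not given in the sources used here. Per the file headers, spot intensity was extracted by the authors with Agilent Feature Extraction 11.0.1.1, whose processed signal is background-subtracted and spatially detrended but not normalized between arrays. The deposited flags state which spots are well above background, saturated or outliers. The authors' value table holds log2 values of 26188 probes, with a median of 8.85 in each of 4 columns. Its sorted values were the same in every column and correlated with the log2 processed signal of the same array at 0.999 or more, so that it was read as quantile normalised and not centred per probe. Scale, centring and direction were thus settled from the values, and the tool used is not given in the sources used here. All 26188 listed probes were well above background on all 4 arrays when outlier flags were ignored, out of 26190 such probes.

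Each array held 62976 spots, of which 59305 were no controls, for 56605 probes. The 75th percentile of processed signal was 481 in P1, 480 in P2, 799 in P3 and 453 in P4. Outlier spots, between 122 and 152 per array, were left out, and 0 spots were saturated. The main values were log2 of the processed signal minus the array's 75th percentile, averaged over repeated spots. A RefSeq accession named 32994 probes (58.3%) through a gene table of assembly GRCm38.p6, for 22909 genes; the remaining 23611 probes were not used in gene counts, and no coordinates were used. A gene was represented by its probe with the highest mean. Among genes at least 2-fold apart with several measured probes, the probes differed in sign in 4.55% to 13.4%, depending on the pair.

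A gene entered a pair if well above background on at least 1 of its arrays. A value not well above background was raised to the lowest signal well above background on its array where it was below it, and such differences are bounds, written as "at least". Genes at least 2-fold apart were counted by size alone, since 1 array per subset allows no test. The median difference over all measured genes lay between -0.10 (P3 minus P1) and 0.02 (P4 minus P3). For 31 gene lists and 16 lists of cell type markers, the median difference of measured members was placed among 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression. A list was said to stand apart below the 2.5th or above the 97.5th percentile, as a description of these arrays.

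Groups, comparisons, gene lists and the naming rule were fixed before the data were examined. For each pair with P4 the rule took the 8 genes with the largest difference in each direction measured on both arrays and the 4 with the largest bounds, and for other pairs 4 and 2. A gene was left out where its measured probes differed in sign or its name was a clone or model name. It also took the 8 genes in each direction that set P4 apart, the sorted marker and lineage genes, and up to 4 members of each list per pair. Not all genes so chosen are reported here singly, though list medians and counts include them. The planned normexp correction on mean signals was replaced by one on median signals (offset 50), since the files used here hold no mean signal column. That choice, the handling of locally bright areas and the comparison without the P3 array were made after seeing the data.

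A spot was called raised if at least 2-fold above the same spot on every other array. A spot lay in a locally bright area if enough other spots within 32 position units, which hold a median of 19 spots, were raised. The first form of this rule asked for 3 on every array. It was replaced by the smallest number that under 1% of spots would have at the array's own rate, which is 2 for P1, P2 and P4 and 4 for P3; both forms are reported.

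The counting step was tested on simulated data made from the mean of the 4 arrays, with spot noise as the only noise. In each of 20 runs, 200 of 22909 genes were changed in P4. The changed genes were drawn from the 11836 genes well above background on all arrays, so their recovery does not cover dim genes. Genes simulated at 1.5-fold were called 2-fold apart in 0.75%, those at 3-fold in 97.5% and those at 8-fold in 98.6%. Without any change, a mean of 2.25 genes was called higher and 3.75 lower for P4 minus P1. Further alternatives were quantile normalization, scaling to the median of probes above background on all arrays, genes above background on both arrays, no filter and no floor, the mean over a gene's probes, outlier spots kept, the authors' processed values, a 4-fold threshold and random lists not matched on expression. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.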

Results

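Gene expression was measured in 4 subsets of CD8 T cells sorted from spleen and lymph node of untreated C57BL/6 mice that lack PD-1, the coinhibitory receptor encoded by Pdcd1. The mice were 1 to 3 months old. The subsets were defined by CD44, an adhesion receptor carried at high density after antigen experience, and CD62L, the lymph node homing receptor. P1 was CD44low CD62Lhigh, the phenotype of naive cells, and P2 was CD44high CD62Lhigh, the phenotype of central memory cells. P3 was CD44high CD62Llow, the phenotype of effector and effector memory cells, and P4 was CD44low CD62Llow, the subset that the study set out to characterise. Each subset was hybridised to 1 single-colour array, so no difference has a replicate check and no test between subsets was possible. All 4 arrays lay on 1 slide, and array position and subset cannot be told apart. Probes well above background numbered 28033 in P1, 27827 in P2, 30811 in P3 and 28617 in P4, out of 56605. Repeated spots of a probe well above background had a pooled SD of 0.079 on the log2 scale, so that spot noise alone gives a log2 difference a 95% half-width of 0.22. Most of these probes were bright, with 266 of 280 on the P1 array at a level of 0 or more. For dimmer probes above background the half-width was 0.38 at levels from -3 to 0 and 0.72 below -3. These values cover spot noise within an array and no variation between mice, sorts or labelling reactions.

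Transcripts of Cd44 and of T cell lineage markers were compared first. Cd44 was 0.56 higher in P4 than in P1 on the log2 scale, and the P4 minus P2 and P4 minus P3 differences were -3.51 and -3.37. Cd8a differed by -0.09, 0.16 and -0.14 against P1, P2 and P3, Cd8b1 by -0.44, -0.04 and 0.06, and the T cell receptor subunit gene Cd3e by 0.10, 0.31 and 0.38. Pdcd1, the disrupted gene, gave signal in every subset, with levels of -2.77 in P1, -2.53 in P2, 2.30 in P3 and 2.23 in P4 relative to the 75th percentile of each array. The part of the gene that its probe reads was not compared with the deleted part, so this signal checks neither the genotype nor the labels.

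**Figure D1:**
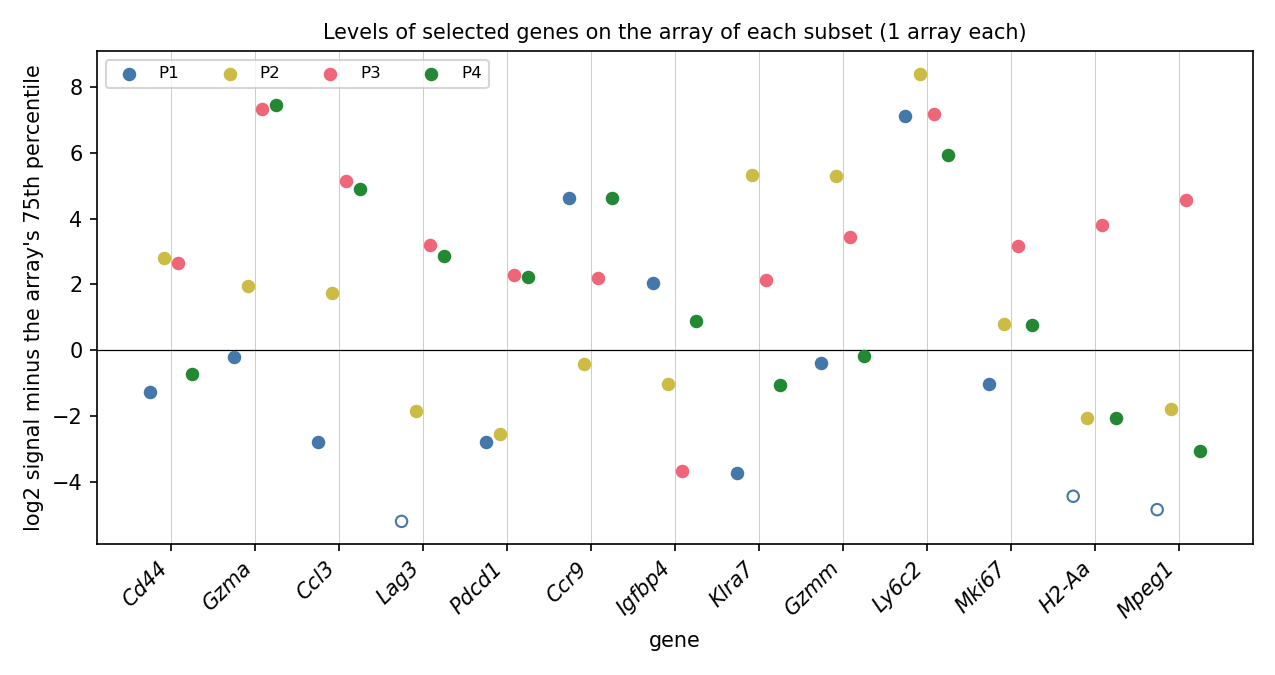
Levels of selected genes (x axis) on the array of each subset, as log2 signal minus the array's 75th percentile (y axis). Each point is 1 array and open points were not well above background. Gzma stood at 7.33 in P3 and 7.44 in P4, while Cd44 stood at 2.65 in P3 and -0.71 in P4.

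P4 was set against P1 to ask how CD44low cells differ when CD62L is low. Genes of cytotoxic and inflammatory effector cells were higher in P4. The chemokine genes Ccl3 and Ccl4 were higher by 7.65 and 6.77 on the log2 scale (201-fold and 109-fold), the granzyme genes Gzma and Gzmb by 7.64 and 6.66 (199-fold and 101-fold), and the calcium-binding protein genes S100a6 and S100a4 by 6.83 and 6.75. Csf1, a macrophage growth factor, was higher by 6.11, and Xcl1, a chemokine that attracts cross-presenting dendritic cells, by 5.67. Genes not well above background in P1 gave bounds: Gzmk was at least 156-fold higher in P4, the opioid precursor gene Penk at least 139-fold, the coinhibitory receptor gene Lag3 at least 128-fold and the adhesion receptor gene Adgrg1 at least 120-fold. In all, 715 of 13160 measured genes were at least 2-fold higher in P4 and 233 at least 2-fold lower.

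Of the 27 measured effector and cytotoxic genes, 18 were at least 2-fold higher in P4 than in P1 and 0 lower, with a list median of 2.81. Of 23 coinhibitory and exhaustion genes, 13 were higher and 0 lower (median 1.80), led by Lag3, by Havcr2, which encodes TIM-3, with a bound of 5.90, by the ectonucleotidase gene Entpd1 at 4.97 and by Tigit at 4.14. Natural killer cell genes, many of which cytotoxic T cells share, had a median of 2.92 with 9 of 10 higher, among them Fcer1g at 4.64. Memory genes had a median of 0.80 with 9 of 20 higher and 2 lower, and regulatory T cell genes one of 0.85 with 4 of 11 higher, such as Ikzf2 at 2.65 and Lrrc32 at 2.98. Cell cycle genes had a median of 0.59, with 7 of 35 higher, such as Tk1 at 2.30 and Mki67 at 1.79. Naive and stem-like genes had a median of -0.56 with 2 of 25 at least 2-fold lower, Dapl1 at -1.44 and Igfbp4 at -1.16. Type I interferon response genes had a median of -0.47 with 0 of 28 past 2-fold. Beside these groups, class II antigen presentation and type 2 dendritic cell genes had a median of 1.24 with 5 of 9 higher, such as H2-Eb1 at 2.37, while B cell and macrophage lists had medians of 0.07 and 0.02. Other cell type lists had medians of 0.69 for plasma cells, 0.59 for innate lymphoid cells, 0.58 for type 1 dendritic cells, 0.40 for plasmacytoid dendritic cells, 0.38 for gamma delta and innate-like T cells and -0.62 for stromal and endothelial cells. All these lists except those of B cells and macrophages lay outside the central 95% of random lists. The plasma cell, plasmacytoid dendritic cell and gamma delta lists no longer did with the mean over probes, the innate lymphoid cell list in the authors' processed values, and the stromal list under quantile normalization.

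Genes lower in P4 than in P1 were fewer and their differences smaller. Pipox, Hjurp and Slc7a4, at -3.33, -2.98 and -2.11, had spots in locally bright areas of the P1 array, as had Calb2, Sval1 and Clec4d among genes with bounds. Tex45 at -2.50, Syt10 at -2.26 and Zc3h12a at -2.44 lay outside such areas, and Zc3h12a encodes Regnase-1, an RNase that limits T cell activation. The counts of 715 and 233 were 420 and 97 in the authors' processed values, 403 and 113 over genes above background on both arrays, 400 and 69 after normexp background correction, 1269 and 877 with no filter and no floor, and 305 and 56 at 4-fold.

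P4 was set against P2 to compare subsets that differ in both markers. Penk, Gzma, Gzmk and Gzmb were higher in P4 by 5.77, 5.49, 5.24 and 4.73, as were the gut homing receptor gene Ccr9 by 5.04 and Septin4 by 5.44. For Ccr9 the level in P4 (4.63) was close to that in P1 (4.62), and the level in P2 was low (-0.41). Adgrg1 was at least 113-fold higher, Csf1 at least 80.5-fold and Havcr2 at least 56.4-fold. Pdcd1 was 4.75 higher, and its spot had raised neighbours on the P4 array, although its level there was close to that on the P3 array (P4 minus P3 -0.07). Ly49 receptor genes were lower in P4: Klra4 at -7.24, Klra16 at -6.57 and Klra7 at -6.36, a family of near-identical genes whose probes can share targets. Cd163l1 (-5.85), the channel gene Aqp9 (-5.60), Dlg5 (-5.58), the granzyme gene Gzmm (-5.47) and Samd3 (-4.49) were also lower. Of 13125 measured genes, 628 were at least 2-fold higher in P4 and 453 lower, against 249 and 370 of the probes without a gene name.

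Memory and virtual memory genes separated P4 from P2, with a median of -1.41 and 12 of 20 measured members lower, including Ccr2 at -3.62, Il18rap at -3.48 and Il18r1 at -2.78. Coinhibitory genes were higher in 11 of 23 and lower in 0 (median 0.88), with Lag3 at 4.69 and Maf at 3.63. Effector genes had a median of 0.56 with 12 of 28 higher and 2 lower. Regulatory T cell genes had a median of 1.41 with 8 of 11 higher, such as Gpr83 at 3.74 and Il2ra at 3.03. Gpr83 stood at 1.61 in P4 and 1.39 in P1 but at -2.13 in P2, so its difference reflects a low P2 level. Cholesterol and fatty acid synthesis genes had a median of 0.38 with 4 of 27 at least 2-fold higher, among them Sqle at 2.30 and Cyp51 at 1.30. Thymocyte genes had a median of 0.57 with 5 of 11 higher, including Dntt at 3.18. The cholesterol and thymocyte lists were lower in P2 than in P1, with medians of -0.31 and -0.43. Their P4 minus P1 medians were 0.04 and -0.003 and did not stand apart. The natural killer cell list had a median of -0.51, which was 0.37 in the authors' processed values, where dim members are not listed. Innate lymphoid cell genes had a median of 1.65, which was -0.62 in the authors' processed values and -0.70 over genes above background on both arrays. Class II and type 2 dendritic cell genes had a median of 0.27 and macrophage genes one of -0.38.

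The largest bounds in this pair, those of Tgm6 and Cd40, came from spots in a locally bright area of the P2 array, as did that of Kynu. The counts of 628 and 453 were 382 and 275 in the authors' processed values, 333 and 229 after normexp, 1171 and 1080 with no filter and no floor, and 188 and 138 at 4-fold.

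P4 was set against P3 to ask how CD62Llow cells differ when CD44 is low. Markers of antigen-presenting cells had the largest differences, all lower in P4: Mpeg1, which encodes perforin-2 of phagocytes, at -7.61, Apol7c at -7.51, Plbd1 at -6.44, Aif1 at -6.17, the cathepsin gene Ctsh at -6.10, Wdfy4 at -5.89, the class II gene H2-Aa at -5.83 and the lectin gene Cd209d at -5.83. Lists fixed for such cells had medians of -3.08 for type 1 dendritic cells (13 of 14 measured members lower) and -4.71 for type 2 dendritic cells and class II (10 of 12). They were -2.17 for macrophages and monocytes (14 of 18) and -1.65 for B cells (8 of 12). Plasmacytoid dendritic cell genes had a median of -1.88, with 6 of 10 lower and 2 higher. The higher ones were Siglech (6.15 in P4, 4.88 in P3) and Ccr9 (4.63 in P4, 2.19 in P3). Globin transcripts were also lower, Hbb-bt at -4.79 and Hba-a1 at -3.67. Of 13988 measured genes, 557 were at least 2-fold higher in P4 and 1267 lower, whereas probes without a gene name split the other way, with 740 higher and 454 lower.

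Among T cell genes, coinhibitory genes had a median of -0.34 with 1 of 23 lower, Tigit at -1.02, and 0 higher. Effector genes had a median of -0.94 with 13 of 28 lower and 0 higher, including Anxa1 with a bound of -4.66, Gzmm at -3.62, S100a4 at -3.20 and Cx3cr1 at -2.96. Memory genes had a median of -1.24 with 13 of 21 lower, such as Ccr2 at -4.86 and Klrk1 at -4.19, and cell cycle genes one of -1.25 with 20 of 37 lower, such as Ccnb2 at -3.33 and Birc5 at -2.77. Beside them, the natural killer cell list had a median of -1.24 with 7 of 13 lower. The innate lymphoid cell list had one of -1.44, which no longer stood apart in the authors' processed values. The gamma delta and innate-like T cell list had one of -0.69. Ccr2 is also a member of the macrophage and monocyte list, and antigen-presenting cell transcripts were higher in P3. The effector, memory and cell cycle differences therefore cannot be assigned to T cells alone. Naive and stem-like genes had a median of 1.01 with 13 of 25 higher and 0 lower, led by Igfbp4 at 4.57, Ccr9 at 2.44, Treml2 at 2.20 and Satb1 at 2.10. Sorcs2 (4.22), Grm6 (3.69), Slc6a19 (3.32) and Ampd1 (3.30) were higher as well, and Wnt5b was at least 17.9-fold higher. Ribosome biogenesis genes had a median of 0.62 with 3 of 29 higher, among them Srm at 1.51. The counts of 557 and 1267 were 288 and 631 in the authors' processed values, 300 and 725 after normexp, 1279 and 1953 with no filter and no floor, and 92 and 511 at 4-fold; over genes above background on both arrays 799 were lower.

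**Figure D2:**
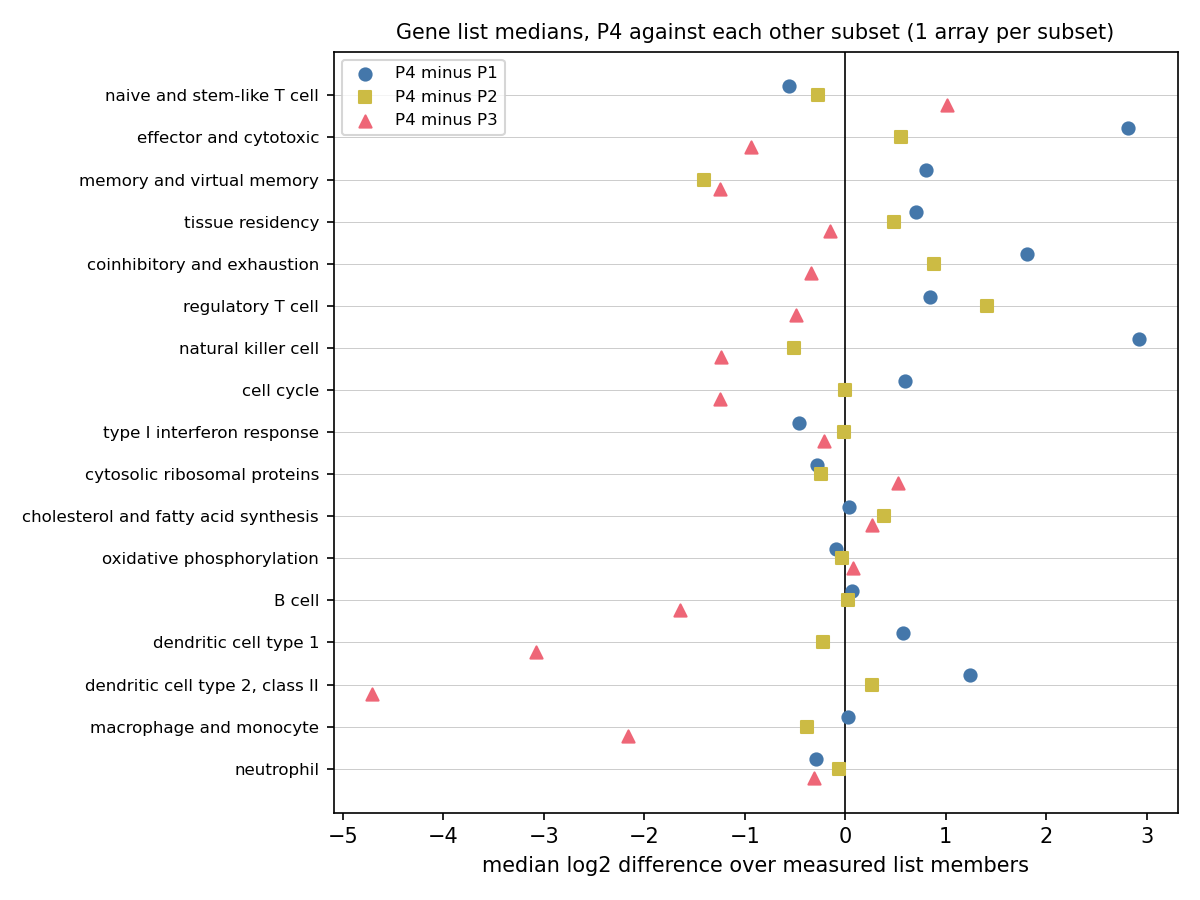
Median log2 difference (x axis) over the measured members of 17 gene lists (y axis) for P4 minus P1, P4 minus P2 and P4 minus P3, each from 1 array per subset. Effector genes lay at 2.81 against P1 and -0.94 against P3, and type 2 dendritic cell genes at -4.71 against P3; the natural killer cell median against P2 is -0.51 here and 0.37 in the authors' processed values, and the ribosomal protein median against P2 turns above 0 under quantile normalization.

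P4 stood apart from every other subset in few genes. At least 2-fold higher in P4 than in each of P1, P2 and P3 were 62 genes, against 963 for P3, 160 for P2 and 98 for P1. Among those with the largest smallest difference, Fam25c, Scgb1b27, Mei1, Dkk2, Ifne, Cgnl1 and Panx2 all had spots in locally bright areas of the P4 array, and 40 genes were left without such areas. At least 2-fold lower in P4 than in each other subset were 13 genes, of which 12 were above background on all arrays. A second measured probe existed for 2 of them, and 1 of these 2 went the same way. Among the 13 were Ly6c2, a memory-linked surface antigen gene, at -1.20, -2.46 and -1.24 against P1, P2 and P3. Its near-identical neighbour Ly6c1 stood at -1.16, -2.37 and -1.21. Zc3h12a was lower by the same order at -2.44, -2.74 and -1.70, Lair1, an inhibitory collagen receptor gene, at -1.07, -2.09 and -2.44, and Aqp9 at -1.58, -5.60 and -2.41. Without the P3 array, 407 genes were at least 2-fold higher in P4 than in both P1 and P2, and 332 of them were also at least 2-fold higher in P3 than in both. Over genes above background on both arrays of each pair the 62 became 7, in the authors' processed values 8, after normexp 20, at 4-fold 12 and with no filter and no floor 186. The 98, 160 and 963 of P1, P2 and P3 became 18, 57 and 407 in the authors' processed values, and 32 and 95 for P1 and P2 without locally bright areas.

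Of 2743 genes at least 2-fold apart between P1 and P3, P4 lay nearer to P1 in 64.7% (exact binomial 95% interval 62.9 to 66.5) and P2 in 76.0% (74.4 to 77.6). The intervals treat genes as independent, which they are not. The P4 share ran from 58.9% with no filter and no floor to 69.6% after normexp. Among the 1759 genes higher in P3 the share was 65.1% for P4 and 80.3% for P2. Among the 984 genes higher in P1 it was 63.9% for P4 and 68.4% for P2. Genes higher in P3 include antigen-presenting cell transcripts, so these shares do not measure how naive P4 cells are.

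The other subsets were compared as a frame for P4. Between the CD62Lhigh subsets, P2 had higher Klra7 (9.06), Klra16 (9.05), Plek (7.15) and Cd163l1 (6.74) than P1, and lower Ccr9 (-5.03), Plaur (-3.62), Gpr83 (-3.52) and the integrin gene Itgae (-3.43). Memory genes had a median of 2.22 with 16 of 20 higher, effector genes one of 2.05 with 18 of 27 higher and 1 lower, as many higher as in P4 against P1, cell cycle genes one of 0.55 with 10 of 36 higher, and coinhibitory genes one of 0.25 with 5 of 21 higher. Beside these, natural killer cell genes had a median of 2.98 with 9 of 12 higher, type 1 dendritic cell genes one of 0.51, and class II with type 2 dendritic cell genes and macrophage genes 0.44 each; the macrophage list no longer stood apart in the authors' processed values or over genes above background on both arrays. Of 12955 genes, 616 were at least 2-fold higher in P2 and 327 lower, against 393 and 208 in the authors' processed values, 340 and 165 after normexp, 389 and 216 over genes above background on both arrays, 1228 and 877 with no filter and no floor, and 240 and 91 at 4-fold.

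P3 had higher S100a4 (9.96), S100a6 (9.27), Apol7c (8.85) and Plbd1 (8.26) than P1, and Lgals3 and Cx3cr1 were at least 630-fold and 448-fold higher. Igfbp4 (-5.73), Sorcs2 (-4.93) and Ampd1 (-3.96) were lower. Effector genes had a median of 4.61 with 24 of 28 higher, and cell cycle genes one of 1.85 with 26 of 37 higher. Beside these, medians were 5.67 for type 2 dendritic cells and class II, and 3.32 for type 1 dendritic cells. They were 2.03 for macrophages and 4.20 for natural killer cells. Further lists that stood apart included plasmacytoid dendritic cells (3.50), regulatory T cells (1.94) and plasma cells (1.81). The same held for innate lymphoid cells (1.77), B cells (1.76) and gamma delta and innate-like T cells (1.76). Of 14088 genes, 1759 were higher and 984 lower, against 1045 and 499 in the authors' processed values and 942 and 203 at 4-fold; 567 were lower after normexp and 1945 with no filter and no floor, and 974 were higher over genes above background on both arrays.

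Against P2, P3 had higher Cx3cr1 (6.98), Penk (6.96), Ly6d (6.53) and Ctsh (6.34), and lower Drc1 (-3.92), Klra4 (-3.67) and Klra16 (-3.64). Coinhibitory genes had a median of 1.16 with 14 of 23 higher, and effector genes one of 2.08 with 20 of 28 higher. Memory genes had a median of 0.16. Beside these, medians were 4.91 for type 2 dendritic cells and class II, and 2.17 for type 1 dendritic cells. They were 1.68 for B cells and 0.53 for natural killer cells. Regulatory T cell genes had a median of 1.75 with 9 of 11 higher. Further lists that stood apart included plasmacytoid dendritic cells (2.64), innate lymphoid cells (1.93), plasma cells (1.86) and macrophages (1.66). Of 14012 genes, 1486 were higher and 786 lower, against 842 and 392 in the authors' processed values, 950 and 456 after normexp and 705 and 146 at 4-fold; 896 were higher over genes above background on both arrays and 1631 lower with no filter and no floor.

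**Figure D3:**
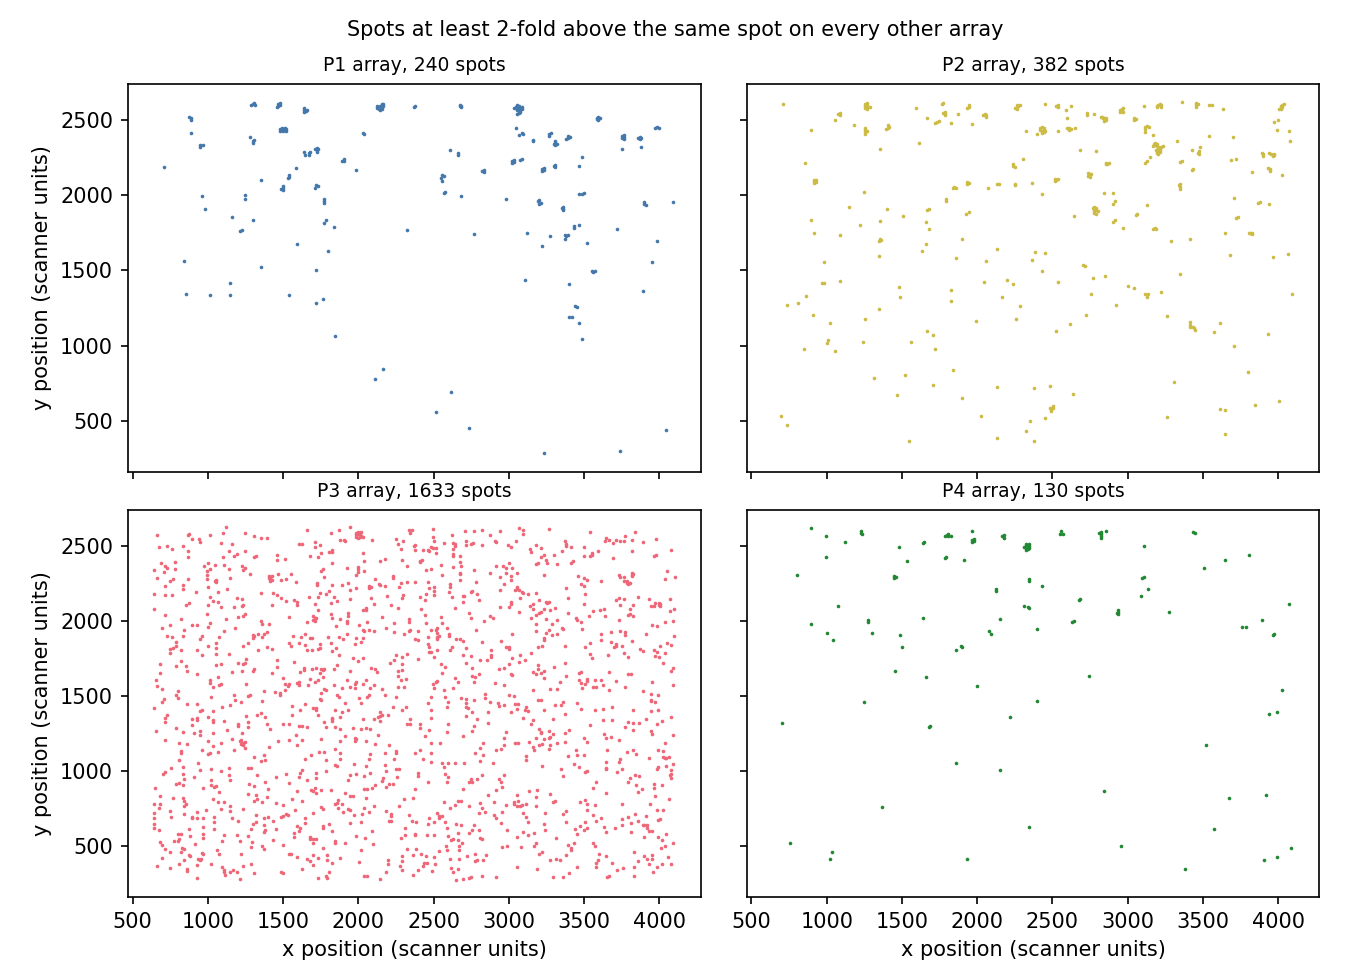
Positions in scanner units (x and y axes) of spots at least 2-fold above the same spot on every other array, 1 panel per array and 1 point per spot. The 130 spots on the P4 array and the 240 on the P1 array lie partly in tight groups, whereas the 1633 on the P3 array are spread over it.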

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

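All tests in this part were chosen after the result was seen, except that of second probes for genes higher in P4 alone. The rule on locally bright areas, which sets the genes that this test covers, was chosen after seeing the data.

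Low CD62L went with opposite differences at low and high CD44 in 19 genes, which were at least 2-fold higher in P4 than in P1 and lower in P3 than in P2, and in 6 genes the other way round; independent lists would share 34.2 and 13.02, so both counts lie below that. On separate arrays, Klra7 differed by 2.69 (P4 minus P1) and -3.19 (P3 minus P2), Klra16 by 2.47 and -3.64, and Klra8 by 2.94 and -1.25, all Ly49 receptor genes with near-identical relatives. Vpreb2 differed by 1.24 and -1.10, Itm2a by 1.57 and -1.09 and Samd3 by 1.07 and -1.19. Krt13, Olfr785, Saa4, Slc26a7, Prl7d1 and Hebp1, also among these genes, had spots in locally bright areas. The differences between the contrasts were not tested, as each rests on 1 array per subset. Outside the named genes, 11591 probes without a gene name were well above background on at least 1 array.

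Antigen-presenting cell transcripts were higher in P3 than in every other subset, with H2-Ab1 at 6.98, H2-Eb1 at 6.34 and Cd74 at 6.20 there. Locally bright areas are argued against, since 0% of the 24 dendritic cell list members that were at least 2-fold higher in P3 than in each other subset lay in one, and a class II programme alone is argued against, since 66.7% of members outside class II presentation (18 of 27) were higher too. Dendritic cells among the sorted cells, some of which carry CD8 alpha, cannot be told apart from expression by T cells by this test. Of all measured members, 70.6% (24 of 34) were higher, between the 75% and the 50% set as limits for and against. That share depends on the rule. Xcr1 and Tlr3, at -3.25 and -3.71 in P3, were above background there alone. They were too near the lowest signal well above background on other arrays to reach 2-fold. Mgl2 and Siglech were bright in every subset (7.23 and 6.12 in P1), so that they could hardly show such cells. Among the 21 members with a level below 0 in each other subset the share was 85.7% (18), but this denominator was picked after the 70.6% was known and decides nothing; 13 members had a level of 0 or more in another subset and 7 belong to a list of another kind. Whether the sort also gated on a T cell receptor marker is not given in the sources used here, and a difference in the biology of P3 cells stays open and untested.

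Genes higher in P4 than in each other subset were few, and locally bright areas may account for a part of them. Of spots raised on the P4 array alone, 53.8% had another such spot nearby, against a mean of 4.28% and at most 11.5% in 100 random placements. Such areas held 21 of the 62 genes under the rule adopted, and leaving them out gave 40 genes; under the rule tried first it gave 48. For genes outside these areas, 83.3% of those with another measured probe (5 of 6 genes) had a second probe in the same direction. In 4 of them it was at least 2-fold higher. This argues only weakly against errors of single spots. A second probe above background in P4 entered, the best of several was taken, and any difference above 0 counted. An expression difference of P4 cells stays open for the genes outside these areas, and array position cannot be told apart from subset.

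By list medians P4 lay between P1 and P3 for effector and coinhibitory genes, though 7 of 23 coinhibitory and 3 of 28 effector genes, among them Gzma, Ccl5, Cd101 and Tnfrsf9, were higher in P4 than in P3 and Anxa1 was not above background in P1 or P4. A uniform admixture of P3 cells in their average composition into P1-like cells is argued against by the share of P3 needed. It was taken over list members at least 4-fold higher in P3 than in P1. Its median was 65.2% over 13 coinhibitory genes (quartiles 59.1 and 78.7) and 10.8% over 18 cell cycle genes (5.06 and 14.9). It was 1.08% over 8 type 1 dendritic cell genes and 29.1% over 21 effector genes. The cell cycle and dendritic cell signal of P3 cannot be assigned to T cells alone. The low shares of these lists therefore do not argue against admixture of P3 T cells without other P3 cells. From Cd44 itself the P3 share was 3.32% (0.94 to 6.41 with spot noise), below the lower quartile of the coinhibitory genes. This limits only cells at the mean P3 level of Cd44 transcript. P4 was sorted as CD44low, so a low share follows in part from the sort and cannot argue against spill-over of cells near the gate. A mixture with a selected part of P3 cells that is low in Cd44 was not tested. A distinct state of P4 cells is a hypothesis that stays open, with no replicate array to bear on it.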

How the results depend on the processing

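Normexp on median signals, both forms of the rule on locally bright areas and the omission of the P3 array were chosen after seeing the data. No paired analysis was possible because each subset has 1 array. The planned normexp correction on mean signals was not run. Counts are given as higher then lower. Quantile normalization, scaling to the median of probes above background on all arrays, outlier spots kept and the mean over probes left all 20 counts within 1.5 times. The authors' processed values shift the median over genes above background on all arrays by 0.13 for P3 minus P1 and 0.11 for P3 minus P2; other scalings shift it by under 0.1.

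With a 4-fold threshold all 20 counts moved: P4 against P1 305 and 56, P4 against P2 188 and 138, P4 against P3 92 and 511, P2 against P1 240 and 91, P3 against P1 942 and 203, P3 against P2 705 and 146. Apart from each other subset were then 38 and 90 for P1, 63 and 9 for P2, 379 and 15 for P3, 12 and 1 for P4. Fewer genes follow from the threshold itself.

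After normexp, P4 against P1 gave 400 and 69, P4 against P2 333 and 229, P4 against P3 300 and 725, P2 against P1 340 and 165, P3 against P1 567 lower, P3 against P2 950 and 456. Genes apart were 38 and 130 for P1, 86 and 25 for P2, 557 and 113 for P3, 20 and 5 for P4. Its offset shrinks differences of dim genes.

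The authors' processed values, which list fewer genes, gave 420 and 97 for P4 against P1, 382 and 275 for P4 against P2, 288 and 631 for P4 against P3, 393 and 208 for P2 against P1, 1045 and 499 for P3 against P1, 842 and 392 for P3 against P2. Genes apart were 18 higher in P1, 57 higher in P2, 407 and 134 in P3, and 8 higher in P4. Over genes above background on both arrays, P4 against P1 gave 403 and 113, P4 against P3 799 lower, P2 against P1 389 and 216, P3 against P1 974 higher and P3 against P2 896 higher. Genes apart were 19 and 179 for P1, 60 higher in P2, 357 higher in P3 and 7 higher in P4.

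With no filter and no floor, where dim probes add noise, P4 against P1 gave 1269 and 877, P4 against P2 1171 and 1080, P4 against P3 1279 and 1953, P2 against P1 1228 and 877, P3 against P1 1945 lower and P3 against P2 1631 lower. Genes apart were 334 and 453 for P1, 375 and 146 for P2, 409 lower in P3, 186 and 75 for P4.

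Leaving out locally bright areas under the adopted rule gave 32 genes apart and higher for P1, 95 for P2 and 40 for P4; the rule tried first gave 46 for P1 and 106 for P2, and 48 for P4, which is within 1.5 times of 62. Without the P3 array, genes apart were 297 and 143 for P2 and 407 and 45 for P4, as fewer subsets are compared.

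The share of genes in which P4 lay nearer to P1 (64.7%) was 59.2% at 4-fold, 58.9% with no filter and no floor, 67.2% with the mean over probes, 69.6% after normexp and 66.8% without locally bright areas; the cause was not tested.

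Of 3037 list medians under alternatives, 2820 kept their side of the percentile bounds, 139 no longer stood apart, 73 newly did and 5 reversed. The chemokine list reversed for P4 minus P1, at -0.36 over genes above background on both arrays and -0.31 in the authors' values. The innate lymphoid cell list reversed for P4 minus P2, at -0.70 and -0.62 in the same settings, and the natural killer cell list for P4 minus P2 at 0.37 in the authors' values. Dim members drop out of both settings. Of 10888 values of named genes, 9648 stayed within 0.22 of their value and 1227 moved. Some settings could move none: 910 values over genes above background on both arrays, and 1164 under median scaling, a small constant shift per pair. With outlier spots kept all 1164 stayed too, as few spots were flagged. A gene with 1 probe could not move under the mean over probes. The 9648 thus include values with little or no room to change. Normexp moved 616 values and left 546. The remaining 13 values reversed, all under the mean over probes, where other probes of the gene differ. These were Cgnl1 (-1.10 in P4 minus P1, -1.19 in P4 minus P2, -0.42 in P4 minus P3), Panx2 (-0.068 in P4 minus P2), Arpp21 (0.79 in P4 minus P1, 1.03 in P2 minus P1, 0.27 in P3 minus P1), Il1rl1 (1.31 in P4 minus P3), Cdkn2a (-0.38 in P4 minus P1, -0.46 in P4 minus P2, -0.053 in P3 minus P1, -0.14 in P3 minus P2) and Mpeg1 (-0.70 in P4 minus P1). Signal over background limits dim genes: spot noise alone gives a log2 difference a half-width of 0.72 for probes above background at levels below -3 and 1.11 for probes not above background.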

Other observations

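The comparisons in this part were chosen after the data were examined. The CD62L difference could be taken on separate arrays at low CD44 (P4 minus P1) and at high CD44 (P3 minus P2). Over 12815 genes, 513 were at least 2-fold higher with low CD62L in both, from 673 and 1120, where independent lists would share 58.8, and 65 were lower in both, from 149 and 652, against 7.58. The shared higher genes were led by Penk (7.12 and 6.96), Adgrg1 (6.90 and 6.76), Gzmk (7.28 and 6.13) and Csf1 (6.11 and 6.18), with the regulatory cytokine gene Il10 at 4.69 and 4.60 and Entpd1 at 4.97 and 4.24; several are bounds. The correlation across genes was 0.62, and genes are not independent replicates.

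The CD44 difference was likewise taken at high CD62L (P2 minus P1) and at low CD62L (P3 minus P4). Over 12586 genes, 302 were at least 2-fold higher with high CD44 in both, from 547 and 767 (33.3 for independent lists), and 112 were lower in both, from 257 and 471 (9.62). The correlation across genes was 0.46. Genes higher in both included Klrk1 (5.75 and 4.19) and Cd44 (4.06 and 3.37). They also included Ccr2 (3.89 and 4.86) of the macrophage list and Itgax (5.38 and 3.83) of the type 1 dendritic cell list. Cd40 and Ebi3, also shared, had spots in locally bright areas. P3 enters the CD62L and the CD44 contrast with its antigen-presenting cell transcripts. Neither overlap can therefore be read as a T cell programme alone.

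Caspase genes of inflammation were higher in P4 than in P1, Casp1 by 3.02 and Casp4 by 2.54, and lower than in P3, at -1.21 and -1.65. The cell cycle inhibitor gene Cdkn2b differed by 1.80 between P4 and P2 and by -1.44 between P4 and P3. Oxidative phosphorylation genes moved little: 0 of 43 measured members were 2-fold apart in P4 against P1, P2 or P3, with medians of -0.10, -0.03 and 0.08.

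Probes without a gene name split the other way from named genes in every pair except P2 against P1: 616 higher and 1464 lower out of 11181 for P3 against P1, 525 and 1227 out of 11087 for P3 against P2, 740 and 454 out of 11076 for P4 against P3, 249 and 370 out of 10356 for P4 against P2, and 233 and 255 out of 10435 for P4 against P1. For P2 against P1, 326 were higher and 218 lower out of 10302.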
